A study of Homo sapiens with 60 samples.

How the data were processed

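RNA sequencing was measured in 60 libraries of A549 cells, an established human lung carcinoma line, collected 24 h after the start of treatment. The deposited table holds expected counts per Ensembl gene, 1 column per library, for 60675 genes and 60 libraries. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the builds GRCh38 and hg38. The annotation release and any filter on reads are not given in the sources used here. The expected counts were checked for unit: 9.95% of the values carry decimals and the totals per library differ, from 17113963 to 33363661. The values were rounded to whole counts before the fit. No column of the table was left unused, and every line of the table named a gene.

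Symbols, positions and gene types were taken from the gene name table and the GENCODE 29 annotation supplied with the reference, which may differ from the release the submitters used. Of the gene IDs, 56558 were found in the gene name table and a further 497 only in GENCODE 29. For 18981 IDs no symbol was given, and these are named by their ID.

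Libraries were grouped by extract and dose as the labels give them. The fit used 57 libraries in 22 groups of 2 or 3. Okbyeongpung-san, with 1 library per dose, stayed out of the fit and was described by its log2 ratio to the mean of the vehicle libraries, with no test. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these libraries. Differences were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). TMM normalization and filterByExpr left 18396 genes, and a quasi-likelihood F-test, two-sided, was run with 35 residual degrees of freedom. Each contrast was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, over 31 contrasts. These were each of 7 extracts at the high, medium and low dose against vehicle, the high against the low dose within each extract, and 3 differences between extracts of the same library set at the high dose. Errors beside log2 fold changes are standard errors derived from the F-test. Each is the absolute log2 fold change divided by the square root of F. Errors beside CPM (counts scaled by the normalised library total) are standard deviations. Lists of genes were tested with camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists within each contrast. Of 28 lists fixed before the data were examined, 25 had at least 5 tested genes. The xenobiotic receptor targets, the metallothioneins and the alveolar lineage markers had fewer and were not tested. The camera test was also run with an estimated correlation.

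The comparisons, tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. For each high dose against vehicle, the rule took the 6 highest and 6 lowest log2 fold changes past the threshold among genes with a mean log2 CPM of at least 2, a usable symbol and every treated library beyond every vehicle library. It added, for each list past its test, the 3 members with the largest change in the direction of the list. For differences between extracts it took 4 genes in each direction. For the high against the low dose it took only list members and genes named already. For Okbyeongpung-san it took the 5 highest and 5 lowest log2 ratios at the high dose, among genes with a mean CPM of at least 10 that lay outside the vehicle range. The report gives a selection of these genes, preferring those past the threshold whichever single library was left out.

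Alternatives chosen before the data were examined were DESeq2 size factors in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, the replicate number as a block, a threshold of 2-fold, only the libraries of the groups compared, each library left out in turn, and, for the lists, an estimated correlation and fry. For the correlations between extracts they were the high dose against vehicle and a minimum mean log2 CPM of 4, and for Okbyeongpung-san a prior count of 5. Alternatives added after the data were seen were a covariate for the library class described in the report, comparisons inside a class, and offsets that remove each library's smooth trend on GC content and gene length. The offsets were also combined with the replicate block for 1 comparison. Replicate numbers were checked for pairing by the correlation, across genes, of the differences between libraries that share a number. Of 31 comparisons, 18 had 3 such pairs, and only Guibi-tang high against low dose had every correlation above 0.1, so the blocked value is given there. The other comparisons had fewer than 3 pairs or a correlation of 0.1 or less. Single pairs there reached 0.601 in Saengmaek-san high against low dose and 0.632 in Guibi-tang minus Saengmaek-san. In both extracts replicate 2 is of library class 1 and replicate 3 of class 2 at every dose, so a shared number is there also a shared class.

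The procedure was tested on simulated data made from the observed means and spreads, with 18068 genes run for 3 libraries against 3. The changed genes were drawn from those with a mean log2 CPM above 2, so recovery was not measured below that. The simulated libraries held no difference of library class or set, so the false calls do not cover such differences. Of genes changed 1.5-fold, 88.1% were recovered, and of genes changed 2-fold, 95.5%. There were 8 false calls, which is 4.1% of the calls. With 2 libraries against 3, 85.1% and 97% were recovered, with 14 false calls (7%). In a separate simulation a list raised 1.5-fold was called in both and 0 other lists were called. No library was a copy of another replicate of its group, since the lowest chi-square per degree of freedom between replicates was 2.42; pairs across groups were not compared. The depth limits the precision of genes with low counts, which the filter removed. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Libraries of wortmannin and of water extracts, which the description of the series mentions, are not in the deposited table and were not analysed here.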

Results

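RNA sequencing counts were collected from A549 cells, a human lung carcinoma line, after 24 h with ethanol extracts of medicinal herbs and herbal formulas or with vehicle. The vehicle group held 3 libraries. Each extract was given at a high, a medium and a low dose. Polygalae Radix was given at 380, 76 and 15.2 µg/mL and Aucklandiae Radix at 370, 74 and 14.8 µg/mL, each with n = 2 per dose. Menthae Herba, Saposhnikoviae Radix, Saengmaek-san and Guibi-tang were given at 500, 100 and 20 µg/mL with n = 3 per dose. Soyo-san was given at the same doses with n = 2, and Okbyeongpung-san with n = 1. Total expected counts per library ran from 17113963, in Polygalae Radix high dose replicate 2, to 33363661, in Saengmaek-san low dose replicate 1. The vehicle libraries held 26115827, 29712475 and 27715220. The sample labels give the vehicle as 0.1% DMSO, whereas the series description gives 2%, and which was used is not given in the sources used here. The vehicle libraries form a library set of their own and every other set in the labels holds 2 extracts, so each comparison with vehicle is also a comparison of sets. According to the description of the series, samples with too little RNA to give a result were left out by the submitters.

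The libraries fell into 2 classes that the labels do not give. The unnamed gene ENSG00000282955 lay at 3.45 CPM or less in 38 libraries and at 19.1 CPM or more in 22. All vehicle and all Soyo-san and Okbyeongpung-san libraries were in the class with the higher level, called class 2. All Aucklandiae Radix and Menthae Herba libraries were in class 1, and 9 groups held libraries of both. Within these mixed groups, 4577 genes were higher and 4203 lower in class 2 (edgeR). The mitochondrially encoded mRNAs were higher in class 2 by a median of 1.09 on the log2 scale, over 13 genes. Across genes, which are not independent replicates, the class difference had a Spearman rho of 0.45 with GC content and of -0.26 with log2 gene length. Values inside a class, or with class as a covariate, therefore stand beside the comparisons wherever a class holds both groups and the count moves. Inside a class an arm can be a single library, which is then assumed to vary like the other groups, and this is said beside the count. No class holds both Aucklandiae Radix or Menthae Herba and vehicle, and there the class covariate rests on the other groups.

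**Figure D1:**
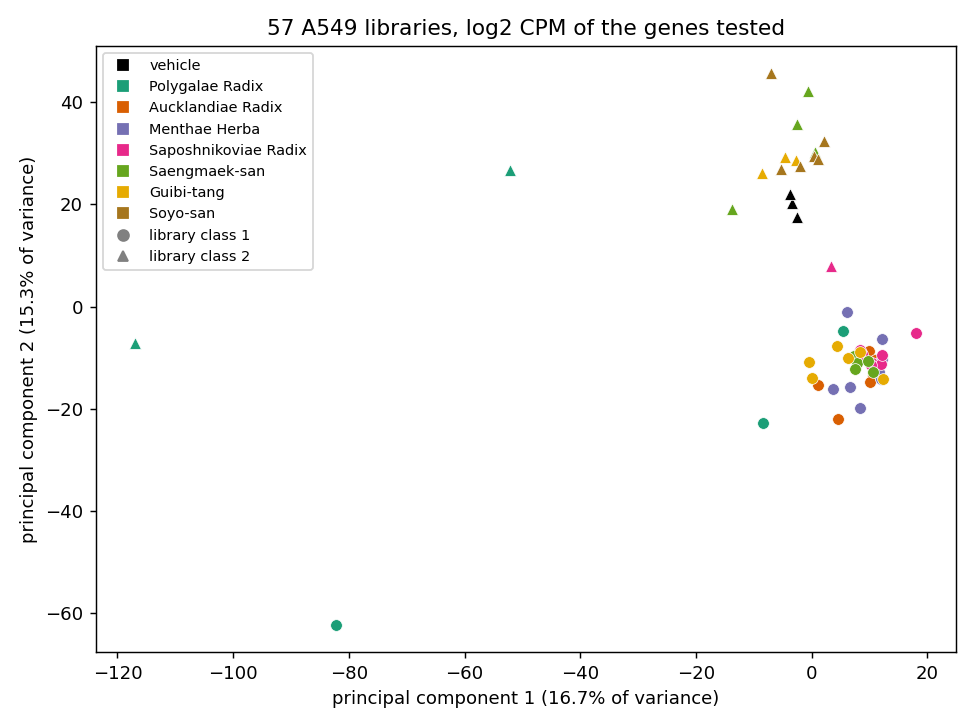
Principal components of log2 CPM of the 57 fitted libraries, with component 1 (16.7% of the variance) against component 2 (15.3%), 1 point per library, marked by extract and library class. The Polygalae Radix high dose libraries lie apart at -117 and -82.3 on component 1, and all class 1 libraries lie below 0 on component 2.

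The first question was which genes each extract changed at its high dose against vehicle. At an adjusted p under 0.05 (edgeR), 10944 genes changed with Polygalae Radix, 6513 with Aucklandiae Radix, 5397 with Menthae Herba and 5227 with Soyo-san. Guibi-tang changed 1716 genes, Saengmaek-san 662 and Saposhnikoviae Radix 166. At 2-fold or more the counts were 3814, 1040, 559, 361, 114, 51 and 20 in the same order. The high dose was also compared with the low dose of the same extract, which uses no vehicle library. That comparison gave 10473 genes with Polygalae Radix, 3360 with Aucklandiae Radix, 2819 with Menthae Herba, 527 with Guibi-tang, 218 with Soyo-san, and 13 each with Saposhnikoviae Radix and Saengmaek-san. Because the counts of the extracts come from groups of different size and class, they were not tested against each other.

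**Figure D2:**
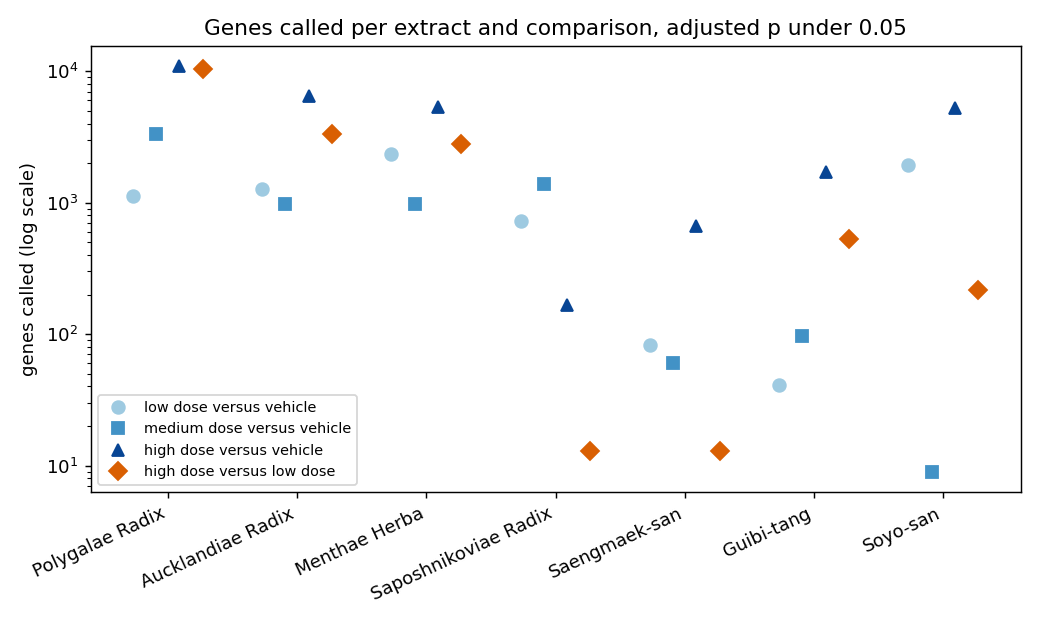
Number of genes past an adjusted p of 0.05 (log axis) for each extract at the high, medium and low dose against vehicle and at the high against the low dose. The counts run from 9 for Soyo-san at the medium dose to 10944 for Polygalae Radix at the high dose.

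At the high dose of Polygalae Radix (n = 2 against 3 vehicle), messages of the heat shock, glycolysis, lipid synthesis and epithelial lists fell. The nuclear receptor genes NR4A2 and NR4A3, which form no tested list, rose. HSP90AA1 (ENSG00000080824, GRCh38 chromosome 14, 102080738 to 102139699), a cytosolic chaperone, went from 2870 ± 21 CPM (SD) in vehicle to 342 ± 45 CPM, a log2 fold change of -3.07 ± 0.08 (SE, adjusted p = 1.52e-30). Of 15 cytosolic heat shock genes 14 fell, with a list median of -1.79 (camera adjusted p = 6.24e-10). The keratins KRT19 (-3.60 ± 0.15, adjusted p = 7.08e-24) and KRT8 (-2.97 ± 0.12) fell with 9 of 10 epithelial genes, at a list median of -1.75. FN1, which encodes fibronectin, changed by -3.22 ± 0.12, and 13 of 14 genes of the TGF-beta and mesenchymal list fell with it. Of 12 glycolytic enzymes 11 fell, among them ENO1 (-2.65 ± 0.12) and PKM (-2.62 ± 0.11), while HK2 rose. All 11 fatty acid synthesis genes fell, with SCD, the stearoyl-CoA desaturase, at -1.68 ± 0.07. Of 23 cholesterol synthesis and uptake genes 21 fell. In the ATF4 and integrated stress response list 14 of 20 genes fell, led by PHGDH (-3.43 ± 0.10) and ASNS (-3.05 ± 0.09), enzymes of serine and asparagine synthesis, whereas ATF3, CEBPB, CTH and DDIT3 rose. NR4A3 (ENSG00000119508, chromosome 9, 99821855 to 99866891) went from 9.2 ± 0.29 to 71.9 ± 9.6 CPM, a log2 fold change of 2.96 ± 0.12 (adjusted p = 8.04e-25). NR4A2 rose by 3.11 ± 0.17 and the nuclear RNA NEAT1 by 2.43 ± 0.22. Of 15 NF-kB and cytokine genes 8 rose, including TNFAIP3 at 1.59 ± 0.13, and TNFAIP2 fell. Of 25 lists 17 passed camera, and 14 of them held with an estimated correlation. The 3 lists lost were the immediate early genes (adjusted p = 0.104 with an estimated correlation), autophagy and lysosome (0.193) and the cytosolic ribosomal proteins (0.467). Within class 2, with 1 high dose library, the count of genes was 10798. In the high against the low dose, 5127 genes rose and 5346 fell, and within class 1, again with 1 high dose library, the count was 10329.

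Aucklandiae Radix at the high dose (n = 2) lowered proliferation genes and raised p53 targets and HMOX1. All 19 mitosis genes fell, with a list median of -0.90 (camera adjusted p = 3.61e-24, and 1.4e-05 with an estimated correlation). The proliferation marker MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) went from 839 ± 19 to 309 ± 21 CPM, a log2 fold change of -1.44 ± 0.14 (adjusted p = 1e-10). KIF20A, a mitotic kinesin, changed by -1.40 ± 0.12. Of 20 DNA replication genes 18 fell, at a median of -0.56. Of 20 p53 targets 15 rose and 0 fell (16 rose adjusted over the list alone), among them BBC3 (1.21 ± 0.13, adjusted p = 1.71e-09), a pro-apoptotic member of the BCL2 family, and FDXR (1.06 ± 0.10). HMOX1, the haem oxygenase (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose from 161 ± 2.3 to 627 ± 36 CPM, by 1.97 ± 0.07. In the autophagy and lysosome list 14 of 17 genes rose, with the cargo receptor SQSTM1 at 0.91 ± 0.06. BIRC3 (1.86 ± 0.12) and NFKB2 (1.22 ± 0.07) were among 7 of 15 NF-kB genes that rose. ANGPTL4, a PPAR target, rose by 1.99 ± 0.11. The mucin genes MUC5B (-2.89 ± 0.33) and MUC5AC (-2.67 ± 0.28) and the small heat shock gene CRYAB (-3.13 ± 0.25) were among the lowest. Of 12 lists past camera 9 held with an estimated correlation, and the 3 lost were the AHR targets (adjusted p = 0.115 with an estimated correlation), the ER unfolded protein response (0.259) and the mitochondrially encoded mRNAs (0.54). With class as a covariate the mitochondrial list had an adjusted p of 0.94. Relative to the low dose, where all libraries are of class 1, 1658 genes rose and 1702 fell, all 19 mitosis genes fell and 16 p53 targets rose. Against vehicle 6820 genes were called with class as a covariate, and 4788 of the 6513 genes called without it were shared. The count against vehicle was 4301 without Aucklandiae Radix high dose replicate 2. The count against the low dose ran from 2070 to 2214 when any 1 of the 4 libraries compared was left out.

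Menthae Herba at the high dose (n = 3) raised integrated stress response genes and AHR targets and lowered lipid synthesis genes. STC2, a secreted glycoprotein (ENSG00000113739, chromosome 5, 173314713 to 173329503), went from 21.6 ± 1.5 to 85.8 ± 21 CPM, a log2 fold change of 1.99 ± 0.10 (adjusted p = 7.1e-19). With it rose CHAC1 (1.91 ± 0.15), a glutathione-degrading enzyme, and the transcription factor DDIT3 (1.79 ± 0.14). In all, 17 of 20 genes of the ATF4 and integrated stress response list rose and 0 fell, with a median of 1.14 (camera adjusted p = 7.24e-24, and 5.92e-05 with an estimated correlation). Of 23 cholesterol genes 17 fell, at a median of -0.47. Of 11 fatty acid synthesis genes 10 fell (11 adjusted over the list alone), with SCD at -1.12 ± 0.06. FN1 changed by -1.65 ± 0.10 within the TGF-beta and mesenchymal list, of which 10 of 14 genes fell. CDH1, the epithelial cadherin, changed by -1.30 ± 0.08, and KRT8, KRT18 and CLDN7 fell with it. ABCA1, a cholesterol transporter and LXR target, changed by -0.95 ± 0.17. The chemokines CXCL2 (1.70 ± 0.17) and CXCL3 (1.72 ± 0.21) rose. MUC5AC changed by -2.89 ± 0.25. Of 14 lists past camera 10 held with an estimated correlation, and heat shock (adjusted p = 0.0517 with an estimated correlation), ribosomal proteins (0.155), autophagy (0.31) and mitochondrial mRNAs (0.442) did not. The autophagy list was called down with a mean of -0.13 but a median of 0.04. For the mitochondrial list the median of -1.06 became 0.02 with class as a covariate. With that covariate 5725 genes were called against vehicle, and 3526 of the 5397 genes called without it were shared. With the low dose as the reference and every library in class 1, 1095 genes rose and 1724 fell, the same 17 of 20 stress response count rose, and 21 of 23 cholesterol genes fell at a median of -0.56. That count of genes was 4236 in a fit with a mean per group and class, which uses the same libraries.

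Saposhnikoviae Radix at the high dose (n = 3) raised the AHR targets CYP1A1 (1.81 ± 0.21, adjusted p = 3.04e-07), CYP1B1 (0.81 ± 0.08), TIPARP (0.70 ± 0.06) and AHRR. The list had a median of 0.62 over 6 genes (camera adjusted p = 5.19e-13, and 4.33e-06 with an estimated correlation). SCD changed by -0.42 ± 0.06 and INSIG1, a regulator of sterol synthesis, by -0.46 ± 0.06. The early response genes NR4A1 (-0.80 ± 0.10), NR4A3 (-0.67 ± 0.12) and BTG2 (-0.66) fell, as did CHAC1 (-0.89 ± 0.17). Of 166 genes called, 96 rose and 70 fell. Against the low dose 13 genes passed, of which CYP1A1, CYP1B1, TIPARP and PREX1 rose and ACSL3, FADS1, FADS2, FGG, FLRT3, INSIG1, NR4A1, SCD and SLC45A4 fell; the full list was chosen for naming after its values were seen. In that comparison the fatty acid synthesis list (median -0.16, camera adjusted p = 4.2e-23) and the cholesterol list (-0.17, 6.7e-20) were lower, with 4 and 1 members past the threshold over all genes and 5 and 11 adjusted over the list alone. Of 12 lists past camera against vehicle 4 held with an estimated correlation, namely AHR targets, fatty acid synthesis, heat shock, and PPAR and fatty acid oxidation. The vehicle count moved with the setting, at 1243 with class as a covariate (162 genes shared) and 416 within class 2 (1 high dose library), and it was 924 without the filter on low counts and 882 with only the 6 libraries compared. It fell to between 57 and 85 without any 1 of vehicle replicates 1, 2 and 3 or Saposhnikoviae Radix high dose replicates 1 and 3. Against the low dose the count was 40 with class as a covariate, 23 within class 1, 7 without high dose replicate 2 and 8 without low dose replicate 1.

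Saengmaek-san at the high dose (n = 3) raised genes of cholesterol synthesis. MVD, the mevalonate diphosphate decarboxylase (ENSG00000167508, chromosome 16, 88651935 to 88663161), rose by 0.62 ± 0.09 (adjusted p = 0.000128), and IDI1, an isomerase of the same pathway, by 0.44 ± 0.08. Of 23 cholesterol genes 15 rose and 0 fell (19 rose adjusted over the list alone), with a median of 0.32 (camera adjusted p = 9.68e-20, and 4.93e-06 with an estimated correlation). ABCA1 changed by -0.78 ± 0.17, a call lost without Saengmaek-san high dose replicate 3. NR4A3 changed by -0.65 ± 0.12. In all, 344 genes rose and 318 fell. With only the 6 libraries compared, MVD (0.61), IDI1 (0.43), ABCA1 (-0.79) and NR4A3 (-0.66) kept their size but missed the threshold (edgeR adjusted p = 0.284 each). Against the low dose 11 genes rose, namely AHRR, CYP1A1, CYP1B1, CYP26B1, ENSG00000280099, FDFT1, INSIG1, SQLE, TIPARP, TM7SF2 and UAP1L1, and NR4A3 and SLC45A4 fell; these were chosen for naming after their values were seen. There the cholesterol list had a median of 0.19 (camera adjusted p = 2.86e-20), with 14 genes higher adjusted over the list alone. Of 12 lists past camera against vehicle 4 held with an estimated correlation, which were cholesterol, AHR targets, LXR targets, and PPAR and fatty acid oxidation. Without Saengmaek-san high dose replicate 2, 7 lists passed camera. The vehicle count was 2833 with class as a covariate (662 genes shared) and 2834 within class 2, but 4 with only the 6 libraries compared. It ran from 186 to 967 when 1 library was left out, and it was moved by vehicle replicates 1, 2 and 3 and high dose replicate 3. With the low dose as the reference it was 58 with class as a covariate, 182 within class 2 (1 low dose library) and 0 within class 1 (1 high dose library, edgeR, with 817 genes at an unadjusted p under 0.05), and it ran from 7 to 44 without 1 of high dose replicates 2 and 3 and low dose replicates 1 and 2.

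Guibi-tang at the high dose (n = 3) raised AHR, stress response and NF-kB genes and lowered keratin, proliferation and lipid synthesis genes. CYP1A1 rose by 2.25 ± 0.20 (adjusted p = 1.66e-10) and CYP1B1 by 1.03 ± 0.08. NIBAN1 (ENSG00000135842, chromosome 1, 184790724 to 184974550) rose from 5.91 ± 0.38 to 12.5 ± 0.7 CPM, by 1.09 ± 0.13. Of 20 ATF4 and integrated stress response genes 9 rose and 0 fell (12 adjusted over the list alone), including ASNS (0.59 ± 0.06) and STC2 (0.58 ± 0.10), at a median of 0.32 (camera adjusted p = 7.45e-07, and 0.0199 with an estimated correlation). Of 15 NF-kB genes 6 rose, and SQSTM1 rose by 0.62 ± 0.06. KRT8 changed by -0.65 ± 0.10 and KRT18 by -0.67. Of 19 mitosis genes 11 fell (13 adjusted over the list alone), with MKI67 at -0.54 ± 0.12. FASN, the fatty acid synthase, changed by -0.60 ± 0.11 and SCD by -0.32 ± 0.06. NR4A1 (-1.17) and NR4A3 (-1.14 ± 0.12) fell. Of 14 lists past camera 12 held with an estimated correlation, and glycolysis (adjusted p = 0.305 with an estimated correlation) and ribosomal proteins (0.427) did not. Against the low dose 169 genes rose and 358 fell, with HMOX1 at 0.68 ± 0.06, SCD at -0.53 ± 0.06 and NR4A1 at -1.06 ± 0.10. Libraries of that comparison that share a replicate number correlated. Replicates 1 and 2 are of class 1 and replicate 3 of class 2 at both doses, so this cannot be told apart from class. With the number as a block the count was 769, with 526 of the 527 genes called in both in the same direction. The vehicle count was 3446 with class as a covariate (1380 genes shared) and 2198 within class 2 (1 high dose library). It ran from 988 to 1412 without 1 library, and vehicle replicates 1, 2 and 3 and high dose replicates 1 and 2 moved it. Relative to the low dose it was 977 with class as a covariate, 584 within class 1, 172 within class 2, which holds 1 library per dose, and 347 without low dose replicate 2.

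Soyo-san at the high dose (n = 2) raised AHR targets and stress response genes. CYP1A1 rose by 2.54 ± 0.22 (adjusted p = 6.25e-11), from 1.25 ± 0.39 to 7.32 ± 1.8 CPM, and CYP1B1 by 0.75 ± 0.09. NUPR1, a stress-induced nuclear protein, rose by 0.91 ± 0.12 and SQSTM1 by 0.77 ± 0.06. NPC2, a lysosomal sterol carrier, rose by 0.72 ± 0.11. KLHL11 changed by -1.56 ± 0.30. Of 20 ATF4 and integrated stress response genes 11 rose and CTH fell, at a median of 0.41 (camera adjusted p = 7.72e-07, but adjusted p = 0.0848 with an estimated correlation). Of 9 lists past camera only the AHR targets (0.0122) held with an estimated correlation. Compared with the low dose, 69 genes rose and 149 fell, and both the AHR targets (3.37e-06 with an estimated correlation) and the stress response list (0.00183) were higher, with NR4A1 at -1.24 ± 0.13 and ASNS at 0.63 ± 0.08. All libraries here, vehicle included, are of class 2. The vehicle count was 7134 within that class and 2655 with offsets for GC content and gene length, and it was 2595 without Soyo-san high dose replicate 2. With those offsets the calls of MVD, MKI67, CENPF, KIF11, HSPA4L, CHORDC1 and MANF against vehicle ended. For the high against the low dose the count was 803 within class 2, 628 with class as a covariate, and 29 to 118 without any 1 of the 4 libraries.

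AHR targets, genes of the aryl hydrocarbon receptor that include detoxifying cytochromes, were compared across extracts in the high against the low dose. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) rose by 2.55 ± 0.25 with Aucklandiae Radix, 1.99 ± 0.18 with Menthae Herba, 1.59 ± 0.20 with Saposhnikoviae Radix, 1.18 ± 0.23 with Saengmaek-san, 2.29 ± 0.20 with Guibi-tang and 2.57 ± 0.26 with Soyo-san. TIPARP, a receptor-induced ADP-ribosyltransferase, rose in the same extracts by 1.36, 1.53, 0.69, 0.38, 0.86 and 0.94. The list passed camera with an estimated correlation in these 6 extracts, with list medians of 0.90, 0.75, 0.62, 0.40, 0.85 and 0.96. For Polygalae Radix the median was -0.01 and the list did not pass, with CYP1A1 at -0.47 ± 0.33 (adjusted p = 0.223). There TIPARP (0.62), AHRR (0.64) and CYP1B1 (0.44) rose, and ALDH3A1 (-3.40) and UGT1A6 (-2.31) fell. UGT1A6, which shares exons with its neighbours, also fell with Aucklandiae Radix (-2.46 ± 0.40) and Guibi-tang (-1.03 ± 0.28). Against vehicle the list median rose in order of dose in 6 of 7 extracts, for example 0.04, 0.29 and 0.62 with Saposhnikoviae Radix at the low, medium and high dose. Some steps in that order were small, with -0.13 and -0.13 at the low and medium dose of Saengmaek-san, -0.12 and -0.08 at those of Aucklandiae Radix, and 0.96 and 0.97 at the medium and high dose of Menthae Herba.

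**Figure D3:**
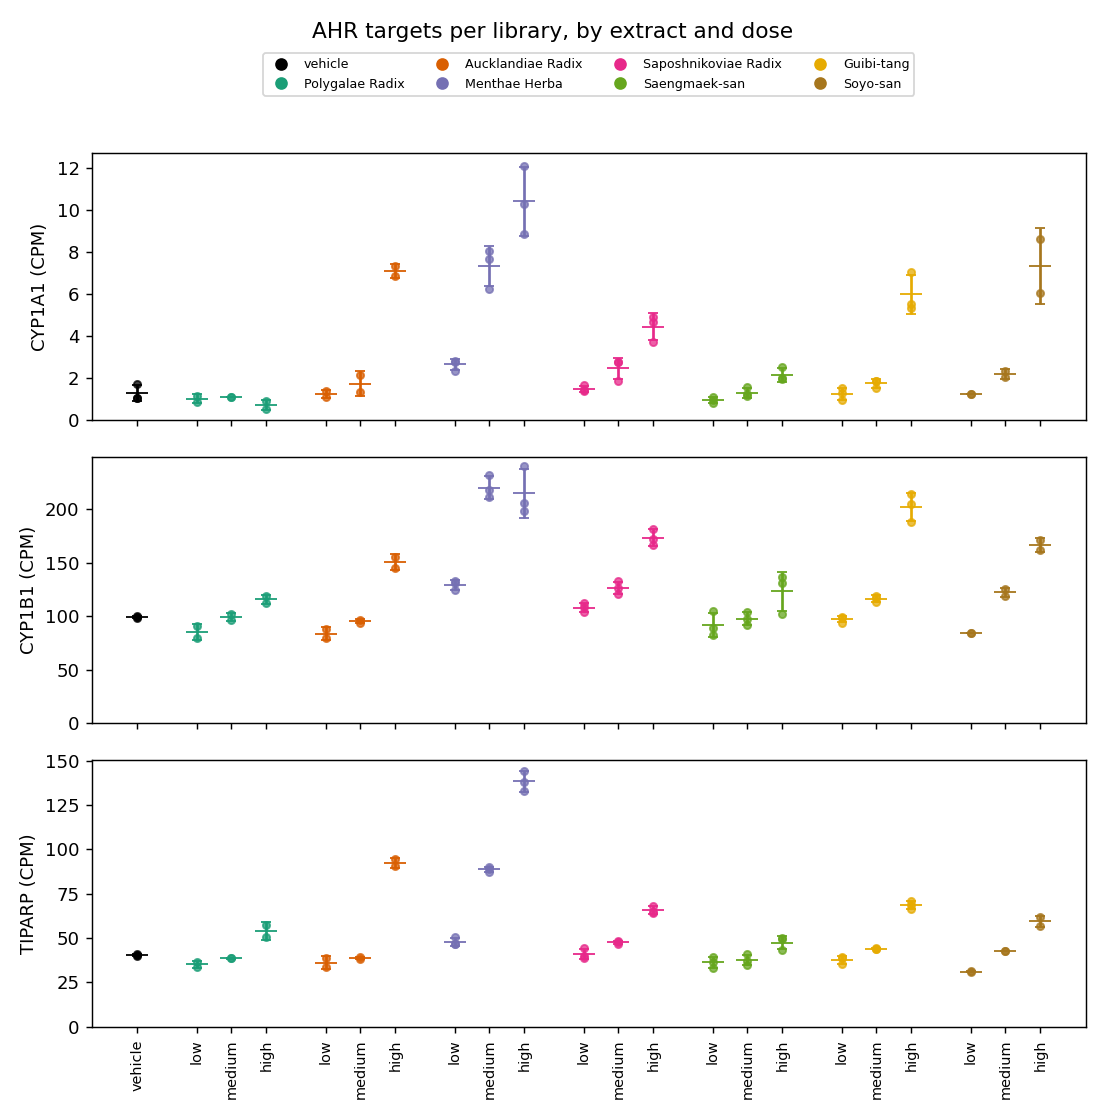
Normalised CPM of CYP1A1, CYP1B1 and TIPARP by extract and dose, 1 point per library, with a line at the group mean and bars of 1 SD. CYP1A1 lies at a mean of 1.25 CPM in vehicle and at 10.4 CPM with Menthae Herba at the high dose.

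**Figure D4:**
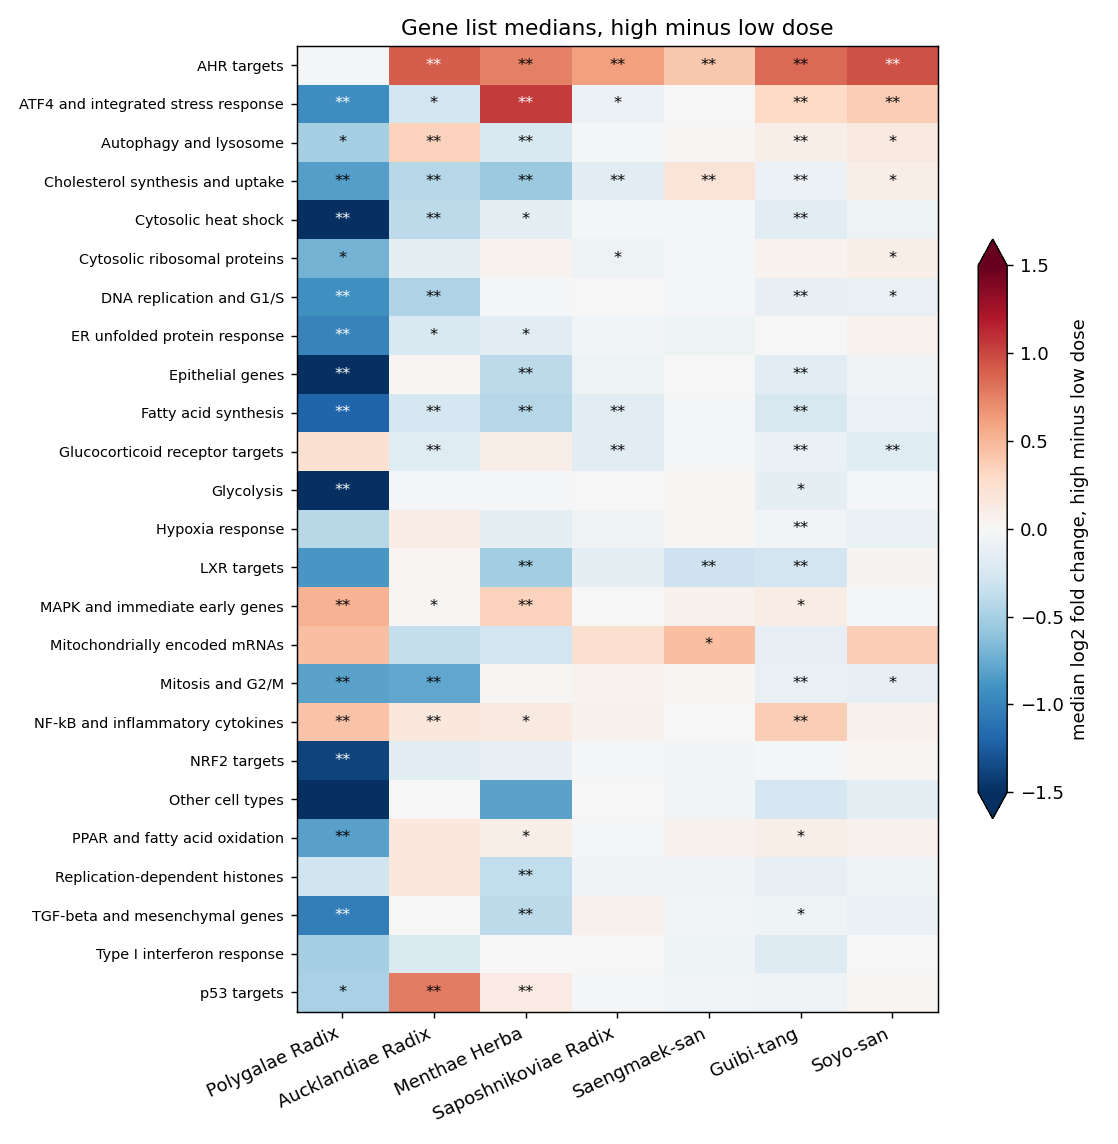
Median log2 fold change of each gene list for the high minus the low dose, as colour with ends at -1.5 and 1.5, by list (vertical axis) and extract (horizontal axis); * marks a list past camera and ** one that also holds with an estimated correlation. The stress response list lies at 1.05 with Menthae Herba and at -0.93 with Polygalae Radix.

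The next comparisons asked where extracts of 1 library set differ at the high dose. Polygalae Radix minus Aucklandiae Radix gave 10664 genes, 5167 higher and 5497 lower, and 10537 within class 1, where Polygalae Radix has 1 library. NR4A3 was higher by 4.34 ± 0.15 (adjusted p = 1.13e-26), NR4A2 by 3.26 ± 0.19 and NR4A1 by 3.02 ± 0.13. MVP, the major vault protein, was at -3.70 ± 0.10 and KRT19 at -3.62 ± 0.16. Of 20 p53 targets 17 were lower, at a median of -1.03 (camera adjusted p = 1.64e-07), and of 17 autophagy and lysosome genes 15 were lower, at -0.80. Glycolysis (-1.79) and epithelial genes (-1.75) were lower as well. Of 20 lists past camera 9 held with an estimated correlation.

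Menthae Herba minus Saposhnikoviae Radix gave 2937 genes, 1133 higher and 1804 lower, and 3250 within class 1. CHAC1 was higher by 2.80 ± 0.16 (adjusted p = 1.22e-17), STC2 by 2.16 ± 0.11 and DDIT3 by 2.02 ± 0.14. Of 20 stress response genes 17 were higher and 0 lower, at a median of 1.17 (camera adjusted p = 3e-37). MUC5AC was at -2.57 ± 0.24 and the basement membrane genes HSPG2 and FRAS1 at -1.93 ± 0.16 and -1.92 ± 0.12. Of 23 cholesterol genes 17 were lower, at a median of -0.35. CYP1A1 was higher by 1.24 ± 0.17. Of 14 lists past camera 10 held with an estimated correlation.

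Guibi-tang minus Saengmaek-san gave 392 genes, 114 higher and 278 lower. Of 23 cholesterol genes 14 were lower (20 adjusted over the list alone), at a median of -0.32 (camera adjusted p = 1.24e-30, and 4.33e-08 with an estimated correlation). NIBAN1 was higher by 1.06 ± 0.13 (adjusted p = 5.92e-07), CYP1B1 by 0.72 ± 0.08 and MAPK11 by 0.76 ± 0.14. KRT4 was at -1.13 ± 0.09, the noncoding RNA H19 at -1.15 ± 0.13 and CRYAB at -1.20 ± 0.18. FADS2 was at -0.58 ± 0.05 among the fatty acid synthesis genes. Of 20 stress response genes 7 were higher (11 adjusted over the list alone). Of 13 lists past camera 10 held with an estimated correlation. The count was 625 with class as a covariate, 178 within class 1 (1 Saengmaek-san library), 204 within class 2 (1 Guibi-tang library), 789 with the GC and length offsets and 725 with the replicate number as a block. It was 207 to 767 without 1 of Guibi-tang high dose replicates 1 and 2 and Saengmaek-san high dose replicate 2.

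At the medium dose against vehicle, genes passed in numbers of 3353 for Polygalae Radix, 980 for Aucklandiae Radix, 974 for Menthae Herba, 1377 for Saposhnikoviae Radix, 60 for Saengmaek-san, 97 for Guibi-tang and 9 for Soyo-san. With Menthae Herba the AHR list had a median of 0.96 (camera adjusted p = 3.43e-15, and 8.91e-07 with an estimated correlation), and CYP1A1 stood at 7.31 ± 0.95 CPM. With class as a covariate the medium dose counts were 1660 for Aucklandiae Radix, 1958 for Menthae Herba, 2765 for Saposhnikoviae Radix, 1428 for Saengmaek-san, 1409 for Guibi-tang and 660 for Soyo-san. Within class 2 they were 5044 for Polygalae Radix, 995 for Saengmaek-san and 265 for Guibi-tang, each with 1 treated library, and 979 for Soyo-san. At the low dose the numbers were 1124, 1269, 2356, 727, 82, 41 and 1933 in the same order. For the lists at the low dose, an estimated correlation left 0 calls in 6 extracts and 1 with Saposhnikoviae Radix, the PPAR and fatty acid oxidation list. These counts moved when single libraries were left out. They fell whichever vehicle library was left out, which a smaller group alone may bring about. At the medium dose, leaving out vehicle replicate 1, 2 or 3 moved every count more than 1.5-fold except that of Polygalae Radix. At the low dose it moved all 7 counts. The low dose count of Soyo-san was 8 without Soyo-san low dose replicate 1, that of Polygalae Radix 80 and that of Aucklandiae Radix 32 without replicate 2 of the low dose. That of Menthae Herba was 462 without low dose replicate 3, that of Saposhnikoviae Radix 140 without low dose replicate 2, that of Saengmaek-san 13 without vehicle replicate 2 and that of Guibi-tang 7 without vehicle replicate 3. With class as a covariate the low dose counts were 2325, 2926, 3784, 1857, 1394, 954 and 3964.

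Formulas were compared with a herb they contain, which is textbook knowledge: Guibi-tang holds Polygalae Radix and Aucklandiae Radix, and Soyo-san holds Menthae Herba. Across 18396 genes, which are not independent replicates, the log2 fold changes of the high against the low dose of Guibi-tang had a Pearson r of 0.11 (rho 0.23) with Polygalae Radix and of 0.13 (0.28) with Aucklandiae Radix. Those of Soyo-san with Menthae Herba had an r of -0.02 (0.08). Among all 21 pairs of extracts these ranked 3, 1 and 20, and Guibi-tang with Menthae Herba, not a constituent, ranked 2 at 0.13. Among genes with a mean log2 CPM of at least 4, r was 0.28, 0.57 and 0.01. Soyo-san with Guibi-tang, not a formula and a constituent, lay above all 3 at 0.60, and Saengmaek-san with Saposhnikoviae Radix, likewise not, above 0.28 and 0.01 at 0.43. Against vehicle r was 0.42, 0.61 and 0.35, where unchanged groups simulated against the same vehicle libraries gave 0.42, 0.44 and 0.42. The covariance was 0.232, 0.255 and 0.156, above the 0.0771, 0.0778 and 0.0776 of the simulation. An r near the simulated one therefore does not show that only the vehicle libraries are shared. Menthae Herba with Aucklandiae Radix, not a formula and a constituent, had a covariance of 0.299 against 0.0787. The simulation held no difference of class or library set, so it does not show what those add to r or to the covariance. Pairs that are not a formula and a constituent reached an r as high, with Saposhnikoviae Radix and Menthae Herba at 0.66 and Guibi-tang and Saposhnikoviae Radix at 0.62. For the high against the low dose with class as a covariate, r of the 3 constituent pairs was 0.12, 0.13 and -0.02. Leaving out 1 library moved r between 0.06 and 0.15, between 0.10 and 0.14, and between -0.07 and 0.03. The r of Guibi-tang with Polygalae Radix was 0.06 without Guibi-tang high dose replicate 3. That of Soyo-san with Menthae Herba was -0.07 without Soyo-san low dose replicate 1, and it changed sign without Menthae Herba low dose replicate 3 (0.0278), Soyo-san high dose replicate 1 (0.0198) or Soyo-san low dose replicate 2 (0.00704).

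Okbyeongpung-san, with 1 library per dose, was described without a test. At the high dose 8 genes lay 2-fold or more from the vehicle mean and outside the vehicle range, at the medium dose 9 and at the low dose 10, where each vehicle library gave 2 genes at 2-fold or more from the mean of the other vehicle libraries. The highest log2 ratios to vehicle at the high dose were those of RN7SL2 (2.00), SLX1A (1.79), RN7SL1 (1.56), CXCR5 (1.22) and ENSG00000269968 (0.99). The lowest were those of ENSG00000265401 (-1.39), ENSG00000280800 (-1.20), PEDS1-UBE2V1 (-1.16), SLX1B (-1.01) and ANKRD1 (-0.98). RN7SL2, SLX1A and RN7SL1 were about as high at the medium (2.21, 2.34 and 1.75) and the low dose (2.04, 1.69 and 1.64). CXCR5 (-0.75) and ENSG00000280800 (0.21) had the other sign at the medium dose, and the other ratios kept their sign at both doses. RN7SL2 lay between 20.8 and 28.6 CPM in the Soyo-san libraries of the same set, and between 5.33 and 10 CPM in vehicle. The AHR targets had a median log2 ratio of 0.56 at the high dose, 0.27 at the medium dose and 0.20 at the low dose. Among 10000 random lists matched on size and mean expression, these lay at percentiles 100, 97.8 and 89.7. The cholesterol list had a median of -0.28 at the high, 0.03 at the medium and 0.10 at the low dose (percentiles 0, 71.7 and 93.7). The heat shock list had medians of -0.23, -0.13 and -0.14 (0, 1.51 and 1.3). Cytosolic ribosomal proteins lay at percentile 100 at every dose, with medians of 0.22, 0.23 and 0.32, highest at the low dose. PPAR and fatty acid oxidation genes lay at 100 at the high dose, with a median of 0.38. Across genes, its high dose ratios had an r of 0.40 (covariance 0.063) with those of Saposhnikoviae Radix, a herb it contains. The shared vehicle libraries alone gave 0.33 (covariance 0.0349) in simulation. That simulation held no difference of class or library set, so it does not show what those add. The high minus low ratios had an r of 0.06.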

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

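Chosen only after the result was seen were the selection of the lists in the next paragraph, the tests of GC content and gene length on the low dose counts, of class as the whole cause of those counts, and of class and dose order on the AHR targets; the other tests were chosen before.

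In 4 lists the difference between 2 extracts of 1 library set at the high dose passed camera, also with an estimated correlation, while the high against the low dose passed in opposite directions in the 2 extracts. The p53 targets differed by a median of -1.03 between Polygalae Radix and Aucklandiae Radix (adjusted p = 1.64e-07, with 17 of 20 genes lower). In the high against the low dose their median was -0.49 (adjusted p = 0.0112, but 0.0549 with an estimated correlation) and 0.77 (5.12e-18). Autophagy and lysosome genes differed by -0.804 between the same extracts (1.27e-06), at -0.50 and 0.35 against the low dose. The integrated stress response list differed by 1.17 between Menthae Herba and Saposhnikoviae Radix (3e-37), at 1.05 and -0.09. The cholesterol list differed by -0.32 between Guibi-tang and Saengmaek-san (1.24e-30), at -0.09 and 0.19. With class as a covariate all 4 differences passed, at -0.94, -0.83, 1.18 and -0.34. What causes these differences was not tested. No group held 4 to 10 libraries, so no single library was tested for lying apart.

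The first pattern weighed was the number of genes called at the low dose against vehicle. In the 4 extracts whose low dose libraries are all of class 1, low dose fold changes followed the class difference of the mixed groups with a median slope of 0.555, so class may contribute. For class as the whole cause, the median fold change of the genes called kept a median of 75.2% of its size with class as a covariate. This does not decide, because the genes were chosen by the same contrast without the covariate, which favours a high share. Summed over the 4 extracts, where a gene can count more than once, only 2749 of the 5476 calls were kept. The fit with the covariate made 10892 calls in all, and the covariate rests there on other groups. For GC content and gene length as the whole cause, the share was 81.3% with offsets (3389 of the 5476 calls kept, 5702 calls in all), under the same limit of chosen genes. The vehicle libraries also form a set of their own, which cannot be told apart from treatment here. A response to the low dose stays open: the low dose change correlated best with the extract's own change from medium to high dose in 1 of 7 extracts, Soyo-san, but the test does not decide (a limit set after the value was seen), because in the other 6 it correlated best with that of Soyo-san alone, and the medium and high dose of Saposhnikoviae Radix and Saengmaek-san differ in class.

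The second pattern was the 1933 genes called with Soyo-san at the low dose, against 9 at the medium dose. The gap depends on the threshold, as 4970 and 2459 genes had an unadjusted p under 0.05 (edgeR). With class as a covariate 3964 and 660 were called, although all these libraries are of class 2. All of the 1933 genes stayed called there, and their median log2 fold change was 0.36 in both fits. The covariate thus raised the count without changing the typical size of these changes. With the GC and length offsets 144 genes were called at the low dose. The median log2 fold change of the 1933 genes in the direction called went from 0.36 (median absolute deviation 0.13) to 0.13 (0.12). A trend on GC content or gene length is therefore a candidate explanation for most of these calls. Without Soyo-san low dose replicate 1 the count was 8, as a cause in a single library predicts, and without replicate 2 it was 893. Because the counts of Polygalae Radix and Aucklandiae Radix, also groups of 2, fell to 80 or 151 of 1124 and to 32 or 439 of 1269 without low dose replicate 2 or 3, a limit set after the value was seen, a single library cannot be told apart from the small group. A biological response to the low dose stays open.

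The third pattern was the higher AHR targets at the high than at the low dose in 6 extracts. Class is argued against, since the high and low dose have the same class make-up in 4 of these, and in 2 of the 2 others, Saposhnikoviae Radix and Saengmaek-san, the list was called with class as a covariate, at medians of 0.65 and 0.44. So is GC content or gene length, since the list median kept 50% or more of its value in 6 of 6 with the offsets. A dose response to the extracts may be the cause, as the list medians against vehicle lay in the order low, medium, high in 6 of 7 extracts, Polygalae Radix being the exception; as low below high is the pattern itself, only the place of the medium dose adds to it, by a gap of 0.01 between neighbouring doses in Saengmaek-san and Menthae Herba. This is a hypothesis, found and tested on the same data.

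Splits of the 6 libraries of a comparison into groups of 3 number 10, too few for a share under 0.05. In fits on those libraries alone (edgeR), the real split and the highest other split gave, at the high dose against vehicle, 8066 and 0 genes with Menthae Herba (8957 and 203 at an unadjusted p under 0.05), 882 and 0 with Saposhnikoviae Radix (3641 and 1549), 4 and 0 with Saengmaek-san (1800 and 813) and 2399 and 1 with Guibi-tang. At the medium dose they gave 5969 and 0 (7164 and 275), 3534 and 0 (5748 and 347), 930 and 1, and 274 and 1 in the same order. At the low dose they gave 3926 and 0 (5973 and 473), 5626 and 1, 388 and 0 (2865 and 1407), and 757 and 4. For the high against the low dose they gave 3036 and 0 with Menthae Herba (5148 and 772), 7 and 2 with Saposhnikoviae Radix (983 and 933) and 162 and 2 with Guibi-tang (1840 and 2223, the other split being the higher). In Guibi-tang, where libraries that share a number correlate, the splits that also part every such pair gave 0 (edgeR). Menthae Herba minus Saposhnikoviae Radix gave 3296 and 0 (5489 and 424). In each of these 1 split, the real one, gave as many genes. With Menthae Herba at every dose and Saposhnikoviae Radix at the medium and low dose against vehicle, the real split itself parts the library classes completely, so these counts do not separate class from treatment.

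In the last comparisons another split gave more genes than the real one. For Saengmaek-san high against low dose the real split gave 0 genes (310 at an unadjusted p under 0.05) and the highest other 1011 (3979), and all 10 splits gave as many as the real one. For Guibi-tang minus Saengmaek-san the real split gave 2 and the highest other 596, and 3 splits gave as many. In both, the split with the highest count parted the library classes completely, which points to a structure of the samples, and the values within class are given with the results. The lists called by the real and the highest other split were, against vehicle at the high dose, 12 and 8 with Menthae Herba, 12 and 2 with Saposhnikoviae Radix, 9 and 6 with Saengmaek-san and 15 and 5 with Guibi-tang. For the high against the low dose they were 17 and 8, 6 and 3, 4 and 3, and 15 and 4, and for the differences between extracts 12 and 8 for Menthae Herba minus Saposhnikoviae Radix and 13 and 6 for Guibi-tang minus Saengmaek-san.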

How the results depend on the processing

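The tests with library class, inside a class and with offsets for GC content and gene length were chosen after the data were seen; the others were chosen before. Depth limits genes with low counts, and leaving out 1 of 2 libraries leaves a lone library that is assumed to vary like the other groups. With DESeq2 size factors every count of genes stayed within 1.5 times the value reported. Of 335 calls of named genes, 333 kept their direction and threshold with DESeq2 size factors, 333 with the DESeq2 Wald test, 317 without the filter on low counts, 312 with library class as a covariate and 315 with the offsets. The remaining calls kept their direction and missed the threshold, except 2 that reversed. A missed threshold is not always a smaller fold, since ABCG1 with Saengmaek-san was at -1.02 both with and without the filter. MT-ATP6 with Menthae Herba at the high dose went to 0.0165 with class as a covariate, and RPL35 with Soyo-san went to -0.0726 with the offsets. With only the libraries of the groups compared, 264 of 310 calls were kept, and with each library left out in turn 1567 of 1848. Leaving out a library and the block were not run for the lists at the medium and low doses. A comparison inside a class gives no value where the class lacks either group. Except where fewer genes or libraries make the difference, the cause was not tested.

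Without the filter on low counts, the high dose against vehicle gave 924 genes with Saposhnikoviae Radix and 1037 with Saengmaek-san. The medium dose gave 1829 with Aucklandiae Radix, 1962 with Menthae Herba, 2217 with Saposhnikoviae Radix, 894 with Saengmaek-san, 782 with Guibi-tang and 336 with Soyo-san. The low dose gave 1998 with Polygalae Radix, 2076 with Aucklandiae Radix, 1824 with Saposhnikoviae Radix, 939 with Saengmaek-san and 613 with Guibi-tang. The high against the low dose gave 127 with Saposhnikoviae Radix, 447 with Saengmaek-san and 508 with Soyo-san, and Guibi-tang minus Saengmaek-san gave 605. With the replicate number as a block, the medium dose gave 95 with Saengmaek-san and 22 with Soyo-san. The high against the low dose then gave 22 with Saposhnikoviae Radix, 55 with Saengmaek-san and 503 with Soyo-san, and Guibi-tang minus Saengmaek-san gave 725. With only the groups compared, the high dose gave 882 with Saposhnikoviae Radix and 4 with Saengmaek-san. With the DESeq2 Wald test, the high dose gave 349 with Saposhnikoviae Radix. The medium dose gave 278 with Saengmaek-san, 272 with Guibi-tang and 160 with Soyo-san. The low dose gave 1701 with Polygalae Radix, 1281 with Saposhnikoviae Radix, 285 with Saengmaek-san and 152 with Guibi-tang, and the high against the low dose gave 28 with Saposhnikoviae Radix and 47 with Saengmaek-san. At 2-fold or more, the high dose gave 3814, 1040, 559, 20, 51, 114 and 361 genes for Polygalae Radix, Aucklandiae Radix, Menthae Herba, Saposhnikoviae Radix, Saengmaek-san, Guibi-tang and Soyo-san. In the same order the low dose gave 94, 104, 159, 59, 9, 3 and 54, since the threshold itself removes genes.

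With class as a covariate, the high dose gave 1243 with Saposhnikoviae Radix, 2833 with Saengmaek-san and 3446 with Guibi-tang. The medium dose gave 1660 with Aucklandiae Radix, 1958 with Menthae Herba, 2765 with Saposhnikoviae Radix, 1428 with Saengmaek-san, 1409 with Guibi-tang and 660 with Soyo-san. The low dose gave 2325, 2926, 3784, 1857, 1394, 954 and 3964 in the order of all 7 extracts. The high against the low dose gave 40 with Saposhnikoviae Radix, 58 with Saengmaek-san, 977 with Guibi-tang and 628 with Soyo-san, and Guibi-tang minus Saengmaek-san gave 625. Several counts inside a class rest on an arm of 1 library, which is assumed to vary like the other groups. These are the class 1 counts of Polygalae Radix high against low dose and of Polygalae Radix minus Aucklandiae Radix, class 2 counts with Polygalae Radix, Saposhnikoviae Radix and Guibi-tang and with Saengmaek-san at the medium and low dose, both classes of Saengmaek-san high against low dose and of Guibi-tang minus Saengmaek-san, and Guibi-tang high against low dose in class 2, with 1 library on each side. Within class 1, the high against the low dose gave 4236 with Menthae Herba, 23 with Saposhnikoviae Radix and 0 with Saengmaek-san (edgeR, 817 at an unadjusted p under 0.05), and Guibi-tang minus Saengmaek-san gave 178. Within class 2, the high dose gave 416 with Saposhnikoviae Radix and 2834 with Saengmaek-san. The medium dose gave 5044 with Polygalae Radix, 995 with Saengmaek-san, 265 with Guibi-tang and 979 with Soyo-san, and the low dose 1850 with Saengmaek-san and 4447 with Soyo-san. The high against the low dose gave 182 with Saengmaek-san, 172 with Guibi-tang and 803 with Soyo-san, and Guibi-tang minus Saengmaek-san gave 204. With the GC and length offsets, the high dose gave 426 with Saposhnikoviae Radix and 2655 with Soyo-san. The medium dose gave 1508 with Menthae Herba, 249 with Saengmaek-san, 250 with Guibi-tang and 28 with Soyo-san. The low dose gave 1158 with Saposhnikoviae Radix, 296 with Saengmaek-san, 112 with Guibi-tang and 144 with Soyo-san. The high against the low dose gave 25 with Saposhnikoviae Radix, 34 with Saengmaek-san and 827 with Guibi-tang, or 1073 with the block as well, and Guibi-tang minus Saengmaek-san gave 789.

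With an estimated correlation, 4 lists were called at the high dose with Saposhnikoviae Radix, 4 with Saengmaek-san and 1 with Soyo-san. Soyo-san high against low dose kept 3, and Polygalae Radix minus Aucklandiae Radix 9. At the low dose against vehicle, class as a covariate gave 5, 1, 1, 5, 2, 4 and 2 lists called in the order of the 7 extracts, where 7, 7, 8, 8, 10, 9 and 2 were called without it. At the medium dose it gave 12, 7, 5, 3, 5, 4 and 4, against 12, 7, 9, 6, 10, 8 and 4 without it, and an estimated correlation left 8, 2 and 3 with Polygalae Radix, Aucklandiae Radix and Menthae Herba and none with the others. With fry, 8, 7, 11, 11, 5, 5 and 7 lists were called at the low dose and 19, 7, 10, 12, 7, 3 and 3 at the medium dose. With fry, which does not compare a list with other genes, 20 lists were called with Aucklandiae Radix and 17 with Soyo-san at the high dose. For the correlations of formula and herb, the high dose against vehicle gave 0.416, 0.612 and 0.351 for Guibi-tang with Polygalae Radix, Guibi-tang with Aucklandiae Radix and Soyo-san with Menthae Herba, and a mean log2 CPM of at least 4 gave 0.28, 0.571 and 0.00691. The last pair changed sign in both.

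When 1 library was left out, the high dose counts ran from 4301 to 5635 with Aucklandiae Radix, 57 to 112 with Saposhnikoviae Radix, 186 to 967 with Saengmaek-san, 988 to 1412 with Guibi-tang and 2595 to 4365 with Soyo-san. The lists called with Saengmaek-san ran from 7 to 12. The medium dose counts ran from 56 to 366 with Aucklandiae Radix, 293 to 377 with Menthae Herba, 122 to 1346 with Saposhnikoviae Radix, 15 to 35 with Saengmaek-san, 23 to 96 with Guibi-tang and 0 to 2 with Soyo-san (edgeR). The counts of 0 came without vehicle replicate 1, Soyo-san medium dose replicate 1 or replicate 2, with 1779, 2142 and 928 genes at an unadjusted p under 0.05. The low dose counts ran from 80 to 434 with Polygalae Radix, 32 to 588 with Aucklandiae Radix, 462 to 2549 with Menthae Herba, 140 to 255 with Saposhnikoviae Radix, 13 to 61 with Saengmaek-san, 7 to 34 with Guibi-tang and 8 to 1196 with Soyo-san. The high against the low dose ran from 2070 to 2214 with Aucklandiae Radix, 7 to 11 with Saposhnikoviae Radix, 7 to 44 with Saengmaek-san, 347 to 403 with Guibi-tang and 29 to 118 with Soyo-san, and the lists called with Saengmaek-san ran from 3 to 7. Guibi-tang minus Saengmaek-san ran from 207 to 767. The correlations ran from 0.0582 to 0.146, from 0.0965 to 0.137 and from -0.0657 to 0.0278 for the 3 pairs of formula and herb, the last changing sign without Menthae Herba low dose replicate 3 (0.0278), Soyo-san high dose replicate 1 (0.0198) or Soyo-san low dose replicate 2 (0.00704).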

Other observations

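The single genes named in this part were chosen after their values were seen, while the list tests were chosen before. The orphan nuclear receptor genes NR4A1 and NR4A3 went apart by extract when the high was set against the low dose. The NR4A genes were not a fixed list and were not tested as a set. NR4A3 rose by 2.96 ± 0.13 and NR4A1 by 1.65 ± 0.12 with Polygalae Radix. Both fell with Aucklandiae Radix (NR4A3 -1.38, NR4A1 -1.35), Menthae Herba (-1.10, -1.20), Guibi-tang (-1.14, -1.06) and Soyo-san (-1.11, -1.24), and NR4A1 fell by 0.68 with Saposhnikoviae Radix and NR4A3 by 0.63 with Saengmaek-san. The MAPK and immediate early list rose with Polygalae Radix (median 0.52, camera adjusted p = 0.00126, and 0.0395 with an estimated correlation), with EGR1 at 2.78 ± 0.29 and FOSB at 2.74 ± 0.29. It also rose with Menthae Herba (0.34, 9.51e-06 and 0.00546), with EGR1 at 2.07 ± 0.24, and there DUSP5, at 1.26 with Polygalae Radix, was at -0.51. The list was called up with Guibi-tang as well (camera adjusted p = 0.0222).

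NRF2 targets fell with Polygalae Radix at the high against the low dose (median -1.39, camera adjusted p = 0.000183, and 0.02 with an estimated correlation). Of 20 genes 13 fell, among them TKT, a transketolase (-2.42 ± 0.11), and the quinone reductase NQO1 (-2.26 ± 0.13), whereas OSGIN1 (1.05), SRXN1 (0.91), ABCC2 (0.37) and GCLC (0.33) rose. LXR targets were lower with Menthae Herba (median -0.52, 0.000377), with ABCG1 at -1.05 ± 0.26, with Saengmaek-san (-0.31, 4.28e-06) and with Guibi-tang (-0.29, 4e-04), and in the last 2 extracts no gene of the list passed over all genes (edgeR), with 4 of 6 lower in each when adjusted over the list alone. Glucocorticoid receptor targets were lower with Aucklandiae Radix (median -0.18, 0.0273), Saposhnikoviae Radix (-0.17, 0.00466), Guibi-tang (-0.11, 0.00122) and Soyo-san (-0.18, 0.00464), and all 4 held with an estimated correlation. SGK1, a kinase gene of that list, fell by 0.80 with Aucklandiae Radix, by 0.46 with Guibi-tang and by 0.41 with Soyo-san.

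Hypoxia genes were lower in Guibi-tang minus Saengmaek-san (median -0.12, camera adjusted p = 4.76e-05, and 0.00406 with an estimated correlation), with LDHA at -0.30, CA9 at -0.78 and ADM at -0.27. Histone genes passed only with Menthae Herba at the high against the low dose (median -0.37, 0.0365 and 0.0455), where H2BC5 was at -0.90 ± 0.12. The type I interferon list did not pass in the 17 comparisons that hold a high dose (camera adjusted p from 0.0672 to 0.927), and it passed with Saengmaek-san at the medium dose against vehicle (median 0.20, 0.0329, but 0.0726 with an estimated correlation). Markers of other cell types passed in Polygalae Radix minus Aucklandiae Radix (0.0495, but 0.135 with an estimated correlation), with ACTA2 at -2.27 ± 0.20, and in Menthae Herba minus Saposhnikoviae Radix (0.0372, but 0.115), with COL3A1 at -1.17 ± 0.14.

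TGFB2-OT1 (ENSG00000281453, chromosome 1, 218442626 to 218443996) was listed at 0 in all 3 vehicle libraries. The fold bounds set each group mean against a floor of 3 counts per vehicle library, so they do not hold for each library. At the high dose the group mean was at least 26.7-fold higher with Polygalae Radix, 83.5-fold with Aucklandiae Radix and 36.4-fold with Menthae Herba. With Saposhnikoviae Radix it was at least 41.9-fold higher, with Saengmaek-san 45.1-fold, with Guibi-tang 30-fold and with Soyo-san 57.3-fold. As the vehicle libraries form a set of their own, treatment cannot be told apart from library set here. TGFB2-OT1 was also listed at 0 in Okbyeongpung-san high dose replicate 1 and Soyo-san low dose replicate 2. At the low dose it was at least 82.5-fold higher with Polygalae Radix, 72.6-fold with Menthae Herba, 43.1-fold with Saposhnikoviae Radix, 52.9-fold with Saengmaek-san and 44.8-fold with Guibi-tang, above the high dose, and 67.7-fold with Aucklandiae Radix. The Menthae Herba low dose libraries lay at 7.27, 3.93 and 13.5 CPM of TGFB2-OT1. With Soyo-san it was at least 13.4-fold higher at the low, 17.5-fold at the medium and 57.3-fold at the high dose. Polygalae Radix high dose replicate 2 held 3 counts and replicate 3 held 184. The signal recognition particle RNA RN7SL2 ran from 40.6 to 276 CPM in class 1 and from 5.33 to 44.5 CPM in class 2.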
